A study of Mus musculus with 18 samples.

How the data were processed

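Total RNA from 18 adipose tissue samples of male C57BL/6J mice on chow was labelled with biotin and hybridised to Affymetrix mouse gene arrays, 1 sample per array. Per the labels, the groups were brown adipose tissue (BAT) of 5 wild-type (control) and 5 FXR mice and white adipose tissue (WAT) of 4 control and 4 FXR mice, all 10 weeks old, with labelled cDNA prepared from 500 ng of RNA. FXR mice carried human FXR, the farnesoid X receptor, in adipose tissue at raised levels. The design text calls the samples of a group biological replicates. The labels give neither the WAT depot nor whether BAT and WAT came from the same mice, and p-values measure only the spread between samples as labelled. The extract text of control BAT 2 and 4 adds a feeding period of 6 weeks.

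The deposited value table holds 1 intensity per probe set and array, and its values lie on a linear scale, from 36.0 to 15980, with no missing value. How the authors summarised, background-corrected and normalized these intensities is not given in the sources used here. Array medians lay between 93.1 and 99.9 in BAT and between 60.5 and 61.7 in WAT, so the tissues had not been brought to 1 common distribution. Intensities within 1.5-fold of an array's 1% quantile made up 28.7% to 34.9% of probe sets on BAT arrays and 58.2% to 62.8% on WAT arrays. Changes of such dim genes are compressed, and more so in WAT. The number of arrays limits the precision.

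Of 34760 probe sets, 21640 had exactly 1 gene symbol in the platform annotation, 1321 had several and 11799 had no listed symbol and are unnamed here. Gene IDs of 21553 of the single-symbol probe sets were found in the reference gene table, and 0 symbols differed from it. For 954 genes with more than 1 probe set, the probe set with the highest mean over all 18 arrays was used, which left 19937 genes. Of the called genes with several probe sets, 15 of 175 in BAT and 0 of 7 in WAT had a probe set of opposite sign. Probe sets with several or no symbols were tested apart.

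The values were kept as the authors normalized them, log2(intensity + 1) was taken, and no gene was removed for low signal. Differences were tested, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and p-values were adjusted after Benjamini-Hochberg over all genes, with a threshold of 0.05. FXR was compared with control within the 10 BAT arrays and within the 8 WAT arrays, the difference of both changes (WAT change minus BAT change) over all 18 arrays with 4 group means, and control BAT with control WAT over 9 arrays. Changes are log2 differences, FXR minus control unless stated, with the standard error (SE) of limma.

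There were 31 gene lists: FXR targets, brown adipocyte thermogenesis, white-selective adipocyte, mature adipocyte, de novo lipogenesis, triglyceride synthesis and lipolysis, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, branched-chain amino acid breakdown, extracellular matrix structure, matrix proteases and inhibitors, adipose progenitor and fibroblast, macrophage, inflammatory mediators, lymphocyte, skeletal muscle, endothelium, mesothelium, epithelium, epididymis, Schwann cell and nerve, erythroid and platelet, hepatocyte, circadian clock, cell cycle, unfolded protein response, NRF2 oxidative stress, insulin signalling and glucose use, hypoxia and angiogenesis, and immediate early genes. A few genes stand in more than 1 list. List shifts were tested two-sided with limma's camera at a preset correlation of 0.01 between genes, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the 31 lists. Camera with an estimated correlation and fry stood beside it. The p-value of fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. With an estimated correlation, only brown adipocyte thermogenesis in BAT and branched-chain amino acid breakdown in WAT held their calls. Counts adjusted over the list alone are given beside those over all genes. An exact permutation test of each list's mean per array was added after the camera results had been compared with other splits of the samples. List means are over log2 values.

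Groups, comparisons, tests, gene lists, the rule for named genes and the other settings listed first below were fixed before the data were examined. The rule named Nr1h4 and Nr0b2 whatever their values, the 8 largest rises and 8 largest falls among called genes whose FXR and control arrays did not overlap (predicted genes, olfactory receptors, small RNAs and receptor segments left out), and up to 3 called members of each list with the smallest adjusted p. For a shifted list with no called member it named 2 members, given as values. It named 5 genes per direction for the difference between tissues and 6 label checks between control tissues. Genes named outside the rule were chosen after their values were seen, and each is marked as such.

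Other settings fixed then were quantile normalization of all 18 arrays, centring each array on its median, the mean of all probe sets of a gene, only genes above the median level, trended robust eBayes, array weights, 1 fit of all arrays, a size threshold of 1.5-fold, a replicate block, the fit without control BAT 2 and 4, and leaving out each array in turn. Settings added after the data were seen were the skeletal muscle list mean as a covariate, the fit without FXR BAT 1, 2 and 4, subtraction of each array's 1% quantile with an offset of 16, and the exact list permutation, without and with centring of each array on its median gene level. The steps were tested on simulated data made from these arrays, with changes planted in 200 of 19937 genes, and of 0.3 log2 units in the other members of the unfolded protein response list (21 in BAT, 20 in WAT): in BAT, 92% of genes changed by 0.5 log2 units and 100% of those changed by 1 were recovered, with 7 list members and 13 false among 212 calls, and in WAT 93% and 100%, with 7 list members and 15 false among 215. The simulated noise was drawn independently for each gene. Changes were planted in full in genes of any level, dim ones included, so recovery of real changes may be lower, above all in WAT.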

Results

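Gene expression was measured in BAT, the fat tissue that burns lipid to make heat, and in WAT, the tissue that stores lipid, of mice with raised human FXR in adipose tissue and of wild-type controls. FXR is a nuclear receptor activated by bile acids. There were 5 arrays per genotype in BAT and 4 per genotype in WAT. Correlations between arrays of a group, across genes, were 0.992 to 0.995 in control BAT, 0.973 to 0.994 in FXR BAT, 0.983 to 0.992 in control WAT and 0.980 to 0.992 in FXR WAT. Mouse Nr1h4, the gene of FXR itself, differed by 0.05 ± 0.03 log2 units in BAT (SE, n = 5 and 5, adjusted p = 0.408, limma with Benjamini-Hochberg). In WAT the difference was 0.03 ± 0.04 (n = 4 and 4, adjusted p = 0.834, limma), and neither passed the threshold. The transgene is human, so the mouse probe set checks the labels only indirectly. Nr0b2, a classical FXR target that encodes the repressor SHP, differed by 0.07 ± 0.04 in BAT (adjusted p = 0.299, limma) and by -0.03 ± 0.05 in WAT (adjusted p = 0.858). Both genes were dim, with group means of 6.17 to 6.26 in BAT and 5.87 to 5.96 in WAT. The lowest median gene level of an array was 6.73 in BAT and 6.08 in WAT. Changes of such dim genes are compressed, so a rise of either gene cannot be excluded.

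The first comparison asked which genes differed between FXR and control BAT. Genes of the extracellular matrix, of fibroblasts and of macrophages were higher in FXR BAT. Cilp, which encodes a cartilage matrix protein, rose 3.82-fold, by 1.93 ± 0.08 log2 units (SE, n = 5 and 5, adjusted p = 3.26e-07, limma with Benjamini-Hochberg). Bgn, encoding the collagen-binding proteoglycan biglycan, rose 3.47-fold, by 1.80 ± 0.10 (adjusted p = 2.97e-06, limma), and Inhba, the subunit of activin A, rose 5.04-fold, by 2.33 ± 0.15 (adjusted p = 1.02e-05). The other large rises among genes whose groups did not overlap were Mfap5 (1.89 ± 0.16), a microfibril protein, Lbp, the lipopolysaccharide-binding protein, with 3.69-fold, the proteoglycan gene Ogn (1.82 ± 0.16), the collagen gene Col14a1 (1.75 ± 0.14) and Sfrp1 (1.69 ± 0.08), a secreted inhibitor of Wnt signalling.

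Of 38 measured genes for extracellular matrix structure, 33 rose, 1 fell and 4 did not pass (34 higher and 1 lower adjusted over the list alone). Mfap4 rose by 1.65, Fbln2 by 1.43 and Thbs2 by 1.40. The member that fell, named after its values were seen, was Postn, encoding periostin (-1.05 ± 0.21). Camera, limma's set test, called the list shifted (adjusted p = 4.25e-27), with adjusted p = 0.0539 with an estimated correlation. Of 18 adipose progenitor and fibroblast genes, 11 rose and 7 did not pass (16 higher adjusted over the list alone), among them the procollagen enhancer Pcolce (1.54), the progenitor receptor Pdgfra (1.39) and the surface marker Thy1 (0.46). That list was called by camera of limma (adjusted p = 7.72e-13), with adjusted p = 0.0539 with an estimated correlation. Of 24 macrophage genes, 22 rose and 2 did not pass (23 adjusted over the list alone), such as Csf1r (0.99), the receptor for macrophage colony-stimulating factor, the oxidase subunit Cybb (0.78) and Gpnmb (0.67). Its call in camera of limma (adjusted p = 3.49e-19) had adjusted p = 0.0539 with an estimated correlation. Of 24 matrix proteases and inhibitors, 12 rose, 1 fell and 11 did not pass (13 higher and 3 lower adjusted over the list alone). The gelatinase Mmp2 rose by 0.93, the macrophage elastase Mmp12 by 0.67 and the plasminogen activator Plat by 0.39. The member that fell was Adam12, named after its values were seen (-0.71). This list was shifted in camera of limma (adjusted p = 8.41e-06), with adjusted p = 0.105 with an estimated correlation. Skeletal muscle genes were also high on FXR BAT 1, 2 and 4, with list means of 10.50, 9.78 and 10.53 against 6.81 to 8.37 in controls. Without these 3 arrays, in a fit added after the data were seen, 31 matrix, 9 fibroblast, 19 macrophage and 9 protease genes rose.

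**Figure D1:**
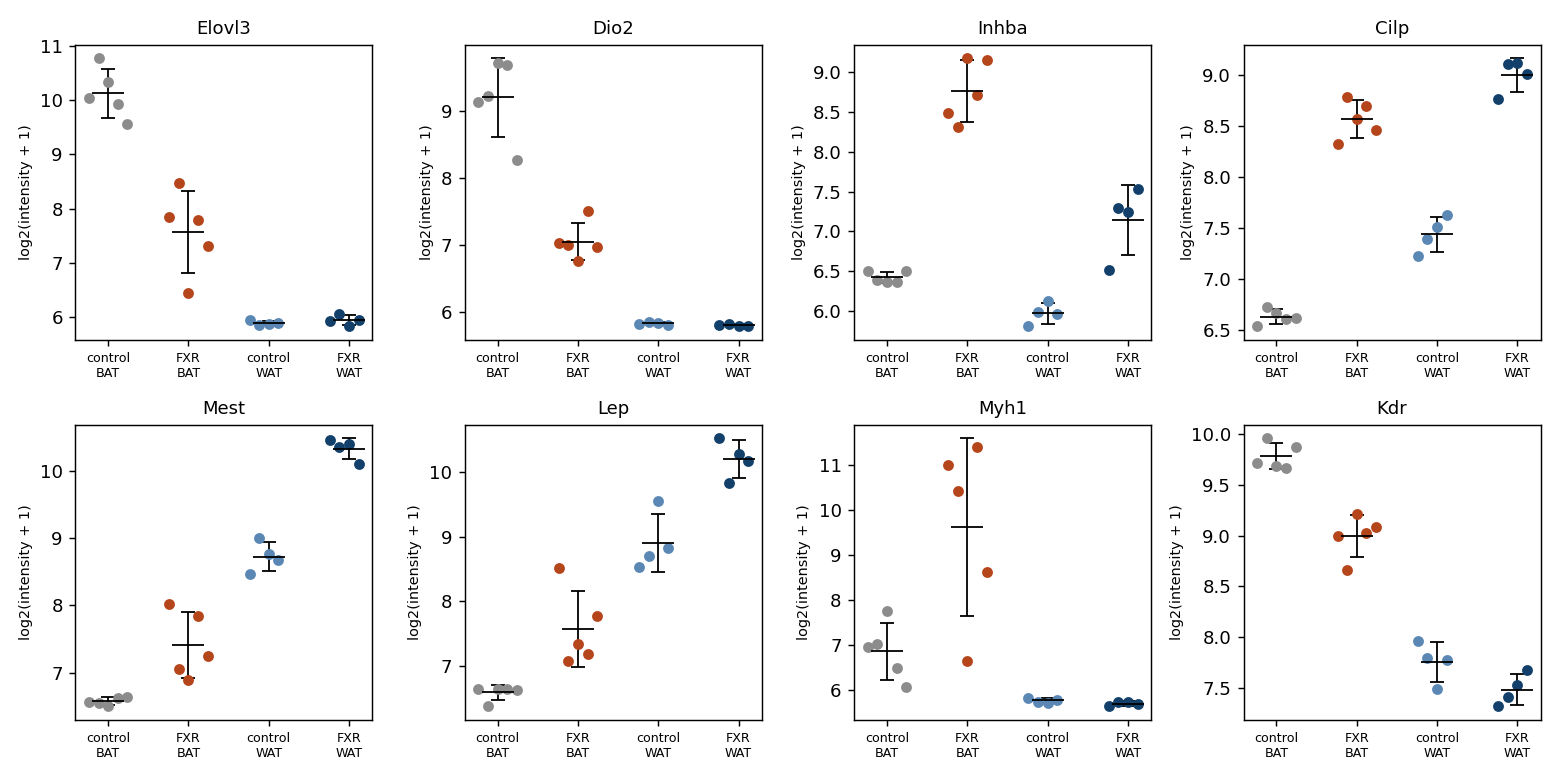
Levels of 8 genes per array, with log2(intensity + 1) on the vertical axes and the groups control BAT, FXR BAT, control WAT and FXR WAT on the horizontal axes; points are arrays, horizontal lines means and bars SD. Elovl3 and Dio2 lie lower on all 5 FXR BAT arrays than on the 5 control BAT arrays, Inhba and Cilp higher in both tissues, and Myh1 varies between FXR BAT arrays with an SD of 1.97.

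Genes for heat production and for mitochondrial and lipid metabolism were lower in FXR BAT. Elovl3, a fatty acid elongase induced by cold, fell 5.88-fold, by 2.56 ± 0.34 log2 units (SE, n = 5 and 5, adjusted p = 5.98e-04, limma). Dio2, the deiodinase that activates thyroid hormone, fell by 2.15 ± 0.25, or 4.44-fold. Other large falls were Gys2 (-1.67 ± 0.26), a glycogen synthase, Ffar4 (-1.49 ± 0.30), a fatty acid receptor, the bicarbonate transporter gene Slc4a4 (-1.39 ± 0.25, 8.39 on FXR BAT 1 against 9.41 to 9.69 on the other FXR arrays), the acyl-CoA synthetase gene Acsl5 (-1.32 ± 0.18), Dhrs9 (-1.15 ± 0.19) and Adcy3 (-1.11 ± 0.16), an adenylyl cyclase. Of 21 genes for brown adipocyte thermogenesis, 16 fell, 1 rose and 4 did not pass (18 lower and 1 higher adjusted over the list alone). Otop1 fell by 0.77 and the cytochrome oxidase subunit gene Cox7a1 by 0.43. Ucp1, the uncoupling protein that makes heat, fell by 0.48, the coactivator gene Ppargc1a by 0.78 and Cidea by 0.37, and Lhx8, a transcription factor gene, rose by 0.21; these 4 genes were named after their values were seen. Camera of limma called this list (adjusted p = 1.22e-12), and the call held with an estimated correlation (adjusted p = 0.0487 with an estimated correlation).

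Of 29 oxidative phosphorylation genes, 23 fell and 6 did not pass (27 lower adjusted over the list alone), including the complex II gene Sdhd (-0.39), the complex III gene Uqcrc1 (-0.30) and the complex I gene Ndufb8 (-0.25). Its call in camera of limma (adjusted p = 9.83e-16) had adjusted p = 0.155 with an estimated correlation. Of 18 genes of branched-chain amino acid breakdown, 15 fell and 3 did not pass (16 adjusted over the list alone), including Dbt (-0.60), the core of the branched-chain ketoacid dehydrogenase, Mccc1 (-0.54) and Pccb (-0.39). That call in camera (limma, adjusted p = 2.41e-12) had adjusted p = 0.155 with an estimated correlation. Of 22 genes for triglyceride synthesis and lipolysis, 14 fell, 1 rose and 7 did not pass (20 lower and 1 higher adjusted over the list alone). The acyltransferase genes Gpam and Dgat1 differed by -0.75 and -0.57 and the lipase gene Lipe by -0.30, and Angptl4, an inhibitor of lipoprotein lipase, rose by 0.42. The list was shifted in camera of limma (adjusted p = 3.75e-11), with adjusted p = 0.0539 with an estimated correlation. Of 20 fatty acid oxidation genes, 14 fell, 1 rose and 5 did not pass (17 lower and 1 higher adjusted over the list alone), with Acadm at -0.46, Acads at -0.41, Eci1 at -0.36 and Cpt1a, the entry enzyme, named after its values were seen, at 0.33. Its camera call (limma, adjusted p = 4.78e-10) had adjusted p = 0.155 with an estimated correlation. Of 20 mature adipocyte genes, 13 fell and 7 did not pass (17 adjusted over the list alone), among them Gpd1 (-0.45) and the lipid droplet gene Plin1 (-0.29). The camera call (limma, adjusted p = 3.16e-09) had adjusted p = 0.0691 with an estimated correlation. Of 17 genes for insulin signalling and glucose use, 9 fell, 1 rose and 7 did not pass (11 lower and 1 higher adjusted over the list alone): Gys1 differed by -0.37, Akt2 by -0.29 and Grb10, an adaptor that inhibits the insulin receptor, by 0.40. The camera call (limma, adjusted p = 3.38e-06) had adjusted p = 0.0539 with an estimated correlation. Muscle gene levels moved with these groups as well. Without FXR BAT 1, 2 and 4, the genes that fell were 12 for thermogenesis, 24 for oxidative phosphorylation, 8 for branched-chain amino acids, 8 for triglycerides, 9 for fatty acid oxidation, 4 for mature adipocytes and 7 for insulin signalling.

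**Figure D2:**
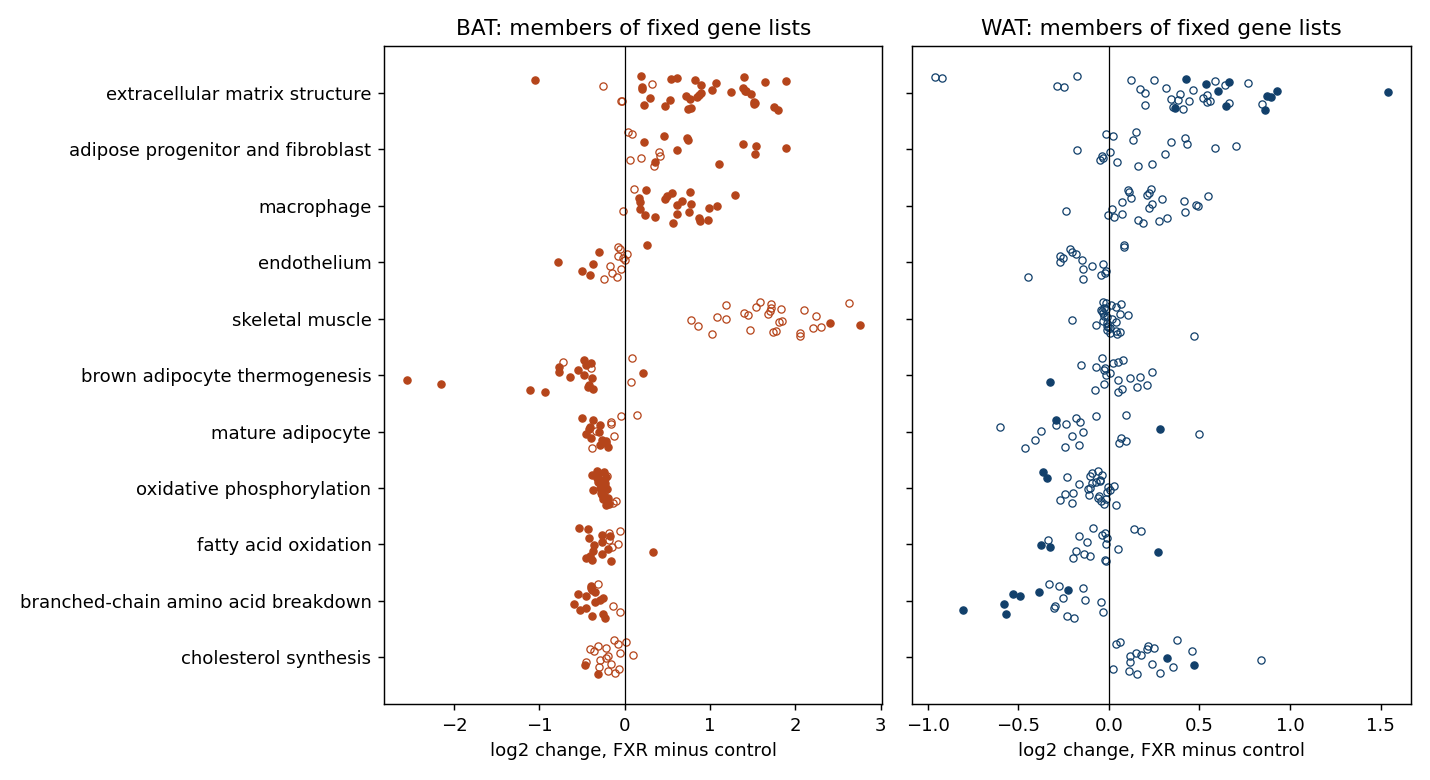
Log2 changes (FXR minus control, horizontal axes) of the members of 11 gene lists in BAT and WAT, each point 1 gene, filled where it passed the threshold in limma. In BAT 33 of 38 matrix genes rose and 23 of 29 oxidative phosphorylation genes fell, and in WAT 11 matrix genes rose and 7 of 18 genes of branched-chain amino acid breakdown fell.

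Among markers of other cell types in BAT, 2 of 29 skeletal muscle genes rose and 27 did not pass (9 higher adjusted over the list alone). These were the myosin genes Myh1 (2.76 ± 0.79 log2 units, adjusted p = 0.0359, limma) and Myh2 (2.41 ± 0.65, adjusted p = 0.0285). Myh1 ranged from 6.65 on FXR BAT 3 to 11.40 on FXR BAT 4. The muscle list was called by camera (limma, adjusted p = 1.37e-07), with adjusted p = 0.460 with an estimated correlation, and without FXR BAT 1, 2 and 4 the difference was -0.018 (median of members, adjusted p = 0.977, limma). Of 17 endothelial genes, 5 fell, 1 rose and 11 did not pass (5 lower and 1 higher adjusted over the list alone): the receptor gene Kdr (-0.78), Eng (-0.50) and Egfl7 (-0.41) were lower and Vwf, named after its values were seen, higher by 0.26. That call (camera of limma, adjusted p = 0.00216) had adjusted p = 0.441 with an estimated correlation, and without the 3 muscle-rich arrays 2 endothelial genes fell. Of 17 genes selective for white adipocytes, 6 rose and 11 did not pass (8 adjusted over the list alone), such as Ccdc80 (1.15) and Mest (0.83), and Lep, encoding leptin and named after its values were seen, rose by 0.99 ± 0.23. This list was shifted in camera (limma, adjusted p = 0.00649), with adjusted p = 0.335 with an estimated correlation, and 4 genes rose without FXR BAT 1, 2 and 4. Of 24 inflammatory mediators, 9 rose and 15 did not pass (9 adjusted over the list alone), with Lcn2 at 0.24, Ccl3 at 0.17 and Ccl2 at 0.16. Its call (camera of limma, adjusted p = 0.00224) had adjusted p = 0.101 with an estimated correlation, and 2 rose without those 3 arrays.

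In BAT, 4 further lists were shifted with few called members. Of 20 cholesterol synthesis genes, 2 fell and 18 did not pass (1 lower adjusted over the list alone), Hmgcs1 by 0.46 and Cyp51 by 0.31. The call (camera of limma, adjusted p = 4.46e-04) had adjusted p = 0.335 with an estimated correlation. Of 20 genes of de novo lipogenesis, 4 fell and 16 did not pass (5 adjusted over the list alone), among them Aacs (-0.66), Acacb (-0.51) and the regulator gene Srebf1 (-0.46). That call (camera of limma, adjusted p = 4.81e-04) had adjusted p = 0.441 with an estimated correlation, and without FXR BAT 3 the mean shift went from -0.25 to -0.17. Without FXR BAT 1, 2 and 4, 9 cholesterol and 11 lipogenesis genes fell. Of 24 cell cycle genes, 4 rose and 20 did not pass (7 adjusted over the list alone), with Mcm4 at 0.19, Cdk1 at 0.17 and Rrm2 at 0.10. This call (camera of limma, adjusted p = 0.00115) had adjusted p = 0.335 with an estimated correlation, and 2 rose without those arrays. No hepatocyte gene of 13 passed with limma (0 adjusted over the list alone, 8 at an unadjusted p below 0.05), with Apoa1 at 0.42 and Hpx at 0.24. The list was still called (camera of limma, adjusted p = 0.00190), with adjusted p = 0.498 with an estimated correlation, and 3 rose without those arrays.

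In all, 3142 of 19937 genes changed in BAT with limma, 1398 higher and 1744 lower (44.5% higher), and 5622 had an unadjusted p below the threshold. Centring each array on its median called 4858 genes, 774 higher and 4084 lower (15.9% higher), and among genes above the median level 35.2% were higher. The median size of a called change was 0.27 log2 units, 318 genes changed at least 1.5-fold (222 higher, 96 lower) and 86 at least 2-fold (74 higher, 12 lower). The groups did not overlap for 2429 genes, 12.2% of all against 0.794% by chance. Camera called 19 of 31 lists, as many as in 9 of 100 splits of the arrays, fry kept 14 and an estimated correlation 1. In the exact permutation of list means, added after the data were seen, 13 lists passed, each with p = 0.00794 (adjusted p = 0.0189), the smallest that 252 arrangements can give. These were the lists for matrix, fibroblasts, macrophages, proteases, thermogenesis, oxidative phosphorylation, branched-chain amino acids, triglycerides, fatty acid oxidation, mature and white-selective adipocytes, insulin signalling and the cell cycle. The median gene level per array was itself 0.079 log2 units higher in FXR BAT, but the median change of single genes was 0.011. Centring each array on its median may thus remove more than a common offset. With this centring, also added after the data were seen, 12 of these 13 lists passed. The cell cycle list did not: its shift went from 0.082 to 0.0030 (exact permutation p = 0.897), and that of inflammatory mediators went from 0.087 to 0.0083. Without control BAT 2 and 4, 1416 genes changed, and without FXR BAT 1, 2 and 4, 1913. Of 87 named BAT genes that passed, 13 lost their call in at least 1 fit with an array left out: Slc51b, Insig2, Vldlr, Cyp51, Myh1, Myh2, Mal, Cnp, Ciart, Cdk1, Rrm2, Nr4a2 and Ccn1. Over all settings 53 of the 87 kept their call. The other 21 that lost it in a setting other than leaving out 1 array were Ffar4, Mest, Plin1, Aacs, Hmgcs1, Ndufb8, Uqcrc1, Pccb, Lcn2, Ccl3, Ccl2, Cd37, Cd52, Il7r, Egfl7, Tef, Mcm4, Hyou1, Txnrd1, Akt2 and Angptl4, with Ccl3 and Ccl2 each losing it in 5 of 11 such settings.

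The second comparison asked the same in WAT, where 265 genes changed. Mest, an imprinted gene linked to adipocyte enlargement, rose 3.04-fold, by 1.61 ± 0.11 log2 units (SE, n = 4 and 4, adjusted p = 0.00135, limma with Benjamini-Hochberg), and Cilp rose 2.95-fold, by 1.56 ± 0.10 (adjusted p = 0.00101). Eln, encoding elastin (1.54 ± 0.28), Mgp, the matrix Gla protein (1.31 ± 0.11), and Lep (1.30 ± 0.22) rose as well. The other large rises were the oxytocin receptor gene Oxtr (1.28 ± 0.18), the reductase gene Mtarc1 (1.25 ± 0.16) and the choline transporter gene Slc5a7 (1.24 ± 0.18, 6.41 on FXR WAT 4 against 7.19 to 7.35 on the other FXR arrays and 1.19 times the floor in controls, so that its size is uncertain). Ifi27l2a, an interferon-induced gene, fell by 1.72 ± 0.17 (adjusted p = 0.00437, limma). Fam13a fell by 1.67 ± 0.24. The remaining large falls were the glutamate transporter gene Slc1a3 (-0.89 ± 0.08), the mitochondrial serine transporter gene Sfxn1 (-0.84 ± 0.08), Btnl9 (-0.84 ± 0.13), the transaminase gene Bcat2 (-0.81 ± 0.08), the clock repressor gene Nr1d1 (-0.69 ± 0.09) and Lgals12 (-0.69 ± 0.11), a galectin of adipocytes.

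Branched-chain amino acid breakdown was the WAT list whose call held with an estimated correlation. Of its 18 genes, 7 fell and 11 did not pass (12 lower adjusted over the list alone), among them Dbt (-0.58 ± 0.05) and Aldh6a1 (-0.56 ± 0.06), and camera of limma gave adjusted p = 1.86e-18 (adjusted p = 0.0201 with an estimated correlation). Of 38 matrix genes, 11 rose and 27 did not pass (28 higher and 4 lower adjusted over the list alone), including Fbln2 (0.93), the collagen gene Col6a2 (0.87) and Col12a1 (0.36). Its call (camera of limma, adjusted p = 4.46e-17) had adjusted p = 0.388 with an estimated correlation. Of 24 proteases and inhibitors, 2 rose, 1 fell and 21 did not pass (6 higher and 1 lower adjusted over the list alone): Mmp2 differed by 0.91, the cathepsin gene Ctsl by 0.66 and Mmp9 by -0.54. That call (camera of limma, adjusted p = 4.98e-05) had adjusted p = 0.388 with an estimated correlation. Of 20 cholesterol synthesis genes, 2 rose and 18 did not pass (7 adjusted over the list alone), Hmgcs1 by 0.47 and Lss by 0.32. The call (camera of limma, adjusted p = 2.35e-09) had adjusted p = 0.388 with an estimated correlation. Of 29 oxidative phosphorylation genes, 2 fell and 27 did not pass (4 adjusted over the list alone), Uqcrc2 by 0.36 and Sdha by 0.34. This call (camera of limma, adjusted p = 3.52e-07) had adjusted p = 0.0534 with an estimated correlation. FXR WAT 1 also showed high levels of some epididymis markers, with Lcn5, named after its values were seen, at 8.43 against a mean of 5.80 on the other 7 WAT arrays. Without that array 105 genes changed, against 109 to 181 without another FXR WAT array and 49 to 336 without a control WAT array.

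Among the remaining shifted WAT lists, fatty acid oxidation had 2 genes that fell, 1 that rose and 17 that did not pass of 20 (5 lower and 1 higher adjusted over the list alone): Eci1 (-0.37), Ech1 (-0.32) and Cpt1a (0.27). The call (camera of limma, adjusted p = 0.00451) had adjusted p = 0.509 with an estimated correlation, and was lost without FXR WAT 1 (mean shift -0.075 to -0.039). Of 20 mature adipocyte genes, Lpl, encoding lipoprotein lipase, rose by 0.28, Pparg, the master regulator of fat cells, fell by 0.29 and 18 did not pass (2 higher and 6 lower adjusted over the list alone). The call (camera of limma, adjusted p = 0.00258) had adjusted p = 0.403 with an estimated correlation. Of 17 insulin signalling genes, 1 fell and 16 did not pass (5 lower and 1 higher adjusted over the list alone), the insulin receptor substrate gene Irs1 by 0.52. Its call (camera of limma, adjusted p = 0.00649) had adjusted p = 0.179 with an estimated correlation. Of 24 inflammatory mediators, the acute phase gene Orm1 (1.17) and the adhesion molecule gene Vcam1 (0.35) rose and 22 did not pass (2 adjusted over the list alone). This call (camera of limma, adjusted p = 0.0202) had adjusted p = 0.572 with an estimated correlation, and was lost without control WAT 2, FXR WAT 1 or FXR WAT 3.

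In 6 shifted WAT lists no gene passed with limma over all genes, and 8 macrophage, 8 fibroblast, 6 lipogenesis, 4 endothelial, 0 cell cycle and 1 mesothelium genes had an unadjusted p below 0.05. Adjusted over the list alone, 5 of 24 macrophage genes, 5 of 18 fibroblast genes and 3 of 20 lipogenesis genes were higher, 1 of 17 endothelial genes was lower, and 0 of 24 cell cycle and 0 of 14 mesothelium genes passed. Values were 0.55 for Lgals3 and 0.23 for Trem2 of macrophages, 0.70 for Pcolce and 0.43 for Pdgfra of fibroblasts, and 1.47 for Scd2 and 0.84 for Insig1 of lipogenesis. The cell cycle list was 6.34 on FXR WAT 4 against 5.98 to 6.04 on the other FXR WAT arrays, and without that array its mean shift went from 0.10 to 0.023 and its call was lost (adjusted p = 0.238, camera of limma). The endothelium call was lost without FXR WAT 1 (mean shift -0.14 to -0.056) and without control WAT 2. The mesothelium call was lost without control WAT 1, control WAT 2 (0.16 to 0.077, but 0.25 without control WAT 3) or FXR WAT 2. The lipogenesis call was lost without control WAT 2, control WAT 3 (0.31 to 0.20), FXR WAT 1 or FXR WAT 2. Gene values were -0.27 for both Kdr and Robo4 of endothelium, 0.26 for Prc1 and 0.13 for Tpx2 of the cell cycle, and 0.36 for Msln and 0.11 for Wt1 of mesothelium. Their camera calls (limma) had adjusted p = 7.36e-07 for macrophages, 0.00369 for fibroblasts, 0.0278 for lipogenesis, 0.00303 for endothelium, 5.33e-04 for the cell cycle and 0.0222 for mesothelium. With an estimated correlation, the adjusted p of camera (limma) was 0.523 for macrophages, 0.551 for fibroblasts and 0.572 for each of the other 4.

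Of the 265 genes changed in WAT with limma, 174 were higher and 91 lower (65.7% higher), and 2491 had an unadjusted p below the threshold. The median size of a called change was 0.40 log2 units, 59 genes changed at least 1.5-fold (46 higher, 13 lower) and 16 at least 2-fold. The groups did not overlap for 1551 genes, 7.78% of all against 2.86% by chance. Camera called 15 of 31 lists, as many as in 4 of 35 splits of the arrays, an estimated correlation kept 1 and fry 3 (branched-chain amino acids, oxidative phosphorylation and insulin signalling). In the exact permutation of list means, added after the data were seen, 0 lists passed and 6 had the smallest unadjusted p that 70 arrangements can give, 0.0286. In this permutation those 6 had adjusted p = 0.148. With so few arrangements a list could pass over 31 lists only if many shared the smallest p. The lack of passing lists therefore says little about WAT. Leaving out 1 array, which also leaves fewer arrays, mostly lowered the count. It was 49 without control WAT 1, 54 without control WAT 2, 336 without control WAT 3 and 64 without control WAT 4. Without FXR WAT 1, 2, 3 and 4 in turn it was 105, 129, 181 and 109. Of 43 named WAT genes that passed, 12 kept their call in every such fit: Mest, Cilp, Mgp, Ifi27l2a, Slc1a3, Sfxn1, Bcat2, Uqcrc2, Dbt, Aldh6a1, Col12a1 and Orm1.

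**Figure D3:**
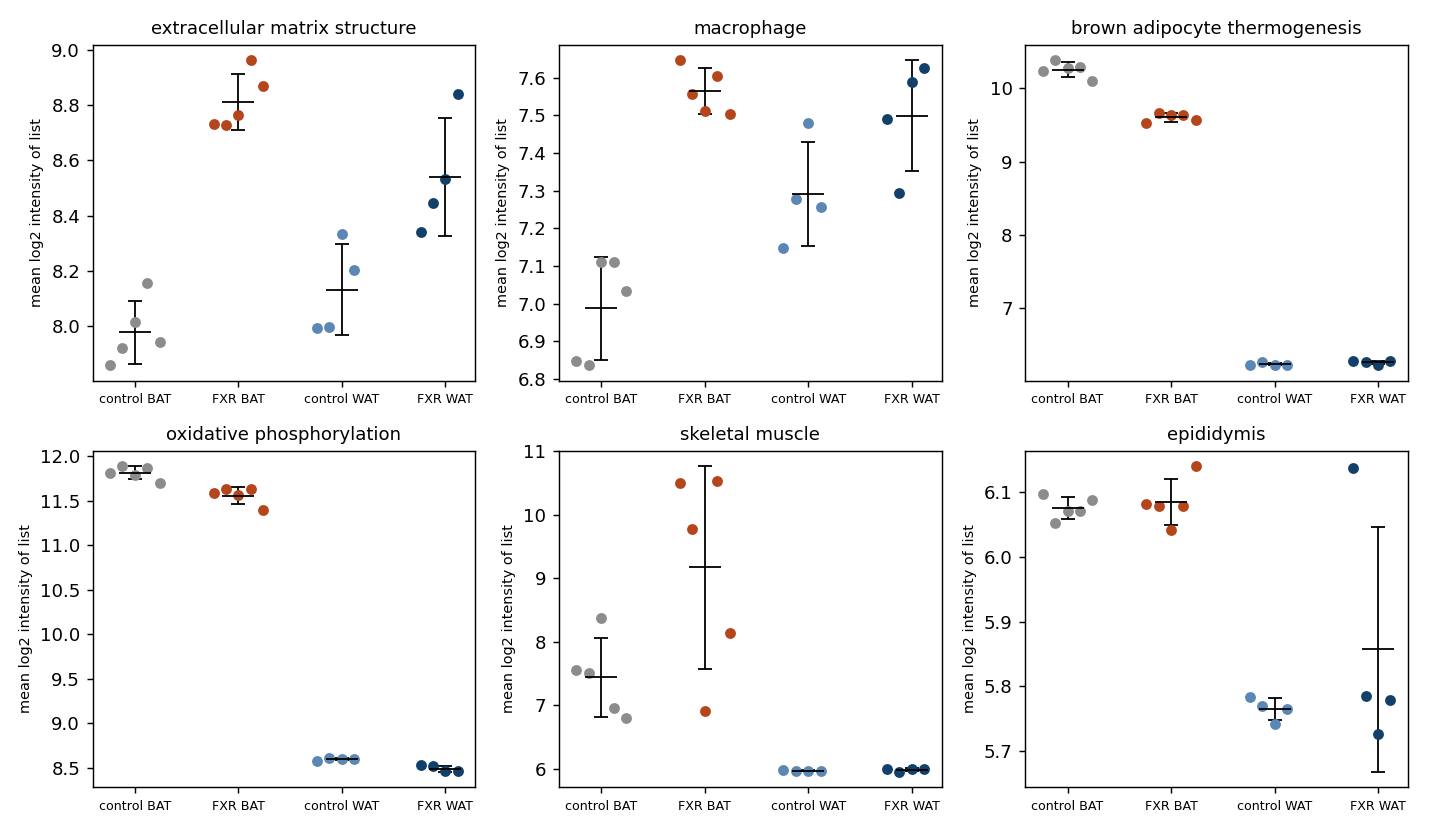
Mean log2 intensity of 6 gene lists on each array (vertical axes) by group (horizontal axes); points are arrays, lines are group means and bars SD. The matrix list averages 8.81 in FXR BAT against 7.98 in control BAT, skeletal muscle spreads from 6.90 to 10.53 over FXR BAT arrays, and the epididymis list is 6.14 on FXR WAT 1.

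The third comparison tested whether the genotype changes differed between the tissues. Gys2 had a fall in BAT, a rise of 0.94 in WAT and a difference, WAT change minus BAT change, of 2.61 ± 0.35 log2 units (SE, adjusted p = 3.67e-04, limma). Elovl3 (2.60 ± 0.41) and Dio2 (2.12 ± 0.30) fell in BAT and had WAT values of 0.05 and -0.03. Their WAT levels of 5.83 to 6.05 and 5.79 to 5.85 were 1.29 and 1.20 times the floor, the 1% quantile of an array, where a fall could not have been seen. The membrane receptor gene Paqr9 (1.99 ± 0.27) fell by 0.76 in BAT and rose by 1.23 in WAT. Orm1 (1.44 ± 0.36, adjusted p = 0.0210, limma) rose in WAT and had a BAT value of -0.27. On the other side stood the matrix genes Thbs2 (-2.36 ± 0.26), Ogn (-1.72 ± 0.23), Thbs4 (-1.66 ± 0.19) and Aspn (-1.50 ± 0.21), which rose in BAT and had WAT values of -0.96, 0.10, -0.03 and 0.08, and Fam13a (-1.60 ± 0.32), which fell in WAT. Thbs4 and Aspn were dim in WAT too, at 1.22 and 1.79 times the floor, where changes are compressed. Without control BAT 2 and 4 the call of Orm1 was lost. In all 1288 genes differed with limma, 885 with the higher change in WAT and 403 with the lower (68.7% higher). Centring each array on its median called 1911, 1669 and 242 (87.3% higher), and without control BAT 2 and 4 the count was 727.

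By list, 14 of 21 thermogenesis genes had a higher change in WAT than in BAT, and of 38 matrix genes 14 had a lower and 3 a higher change. Of fibroblast genes 8 of 18 had a lower change in WAT, and of macrophage genes 6 of 24. For branched-chain amino acid breakdown 0 of 18 differed with limma (4 at an unadjusted p below 0.05). An exact permutation of list means over 17640 arrangements, two-sided, was added after the data were seen. It drew genotype labels within each tissue, so it tests against no genotype change in either tissue. Its p-values therefore cannot decide whether the changes differed between tissues. The differences of 2 lists passed. They were thermogenesis, 0.67 (exact p = 7.94e-04, adjusted p = 0.0228), and cholesterol synthesis, 0.46 (exact p = 0.00147, adjusted p = 0.0228), whose mean change was -0.21 in BAT and 0.25 in WAT. For the matrix list the difference was -0.43 (exact p = 0.224) and for fibroblasts -0.49 (exact p = 0.0540). The thermogenesis list averaged 6.23 to 6.26 on control WAT arrays, against array medians of 5.95 to 5.97 over all probe sets, and a fall is compressed at this signal.

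**Figure D4:**
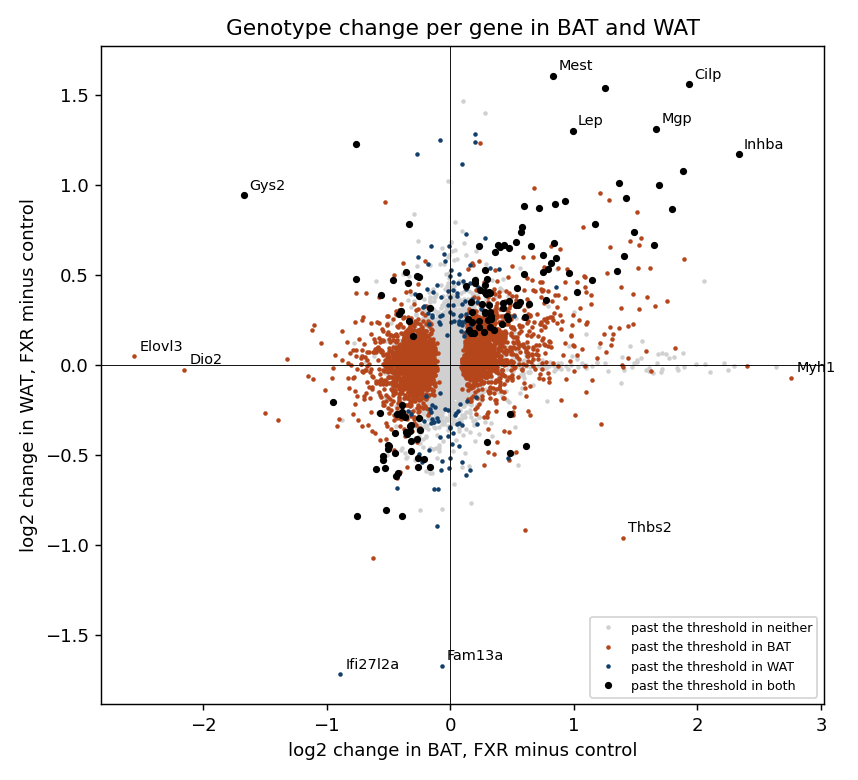
Log2 change (FXR minus control) of each of 19937 genes in BAT (horizontal axis) and WAT (vertical axis); points are genes, coloured by whether they passed the threshold in limma in neither tissue, in BAT, in WAT or in both. Cilp, Mgp, Mest, Lep and Inhba rose in both tissues, whereas Gys2 fell in BAT and rose in WAT.

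Genes called in both tissues were mostly called in the same direction. Of these genes 84 rose in both, against 12.2 if the calls were independent, and 35 fell in both, against 7.96. Opposite calls were 16 genes lower in BAT and higher in WAT, against 15.2, and 4 higher in BAT and lower in WAT, against 6.38, and all 20 passed the test of the difference. The 4 were Podn, Heph, Grb14 and Sctr, named after their values were seen, and the 16 included Gys2, Lpl, Hmgcs1, Hspa5, Sod2 and Vldlr. Across all genes, which are not independent replicates, the changes correlated with r = 0.248 (rho = 0.138, permutation p = 0.0693 over 100 draws of genotype labels, highest absolute r of the draws 0.333), and 53.4% had the same sign. The correlation did not pass, and it did with quantile normalization (r = 0.236, permutation p = 0.0396).

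Control BAT and control WAT differed in the marker genes of their cells. Ucp1 was higher in BAT by 7.46 ± 0.06 log2 units (SE, n = 5 and 4, adjusted p = 1.35e-14, limma) and Cidea by 6.41 ± 0.07, whereas Lep was lower, at -2.32 ± 0.17. The muscle actin gene Acta1 was higher in BAT by 1.98 ± 0.57, and Adam7, an epididymis gene, differed by 0.12 ± 0.07 without passing (adjusted p = 0.114, limma). Hoxc9, a developmental gene of white fat, was higher in BAT by 0.18 ± 0.05, but turned to -0.51 with quantile normalization and -0.49 with centring. The median gene lay 0.59 log2 units higher in BAT, and 19292 genes differed with limma, 18897 of them higher in BAT (98.0%). With quantile normalization 11577 differed, 4714 higher and 6863 lower, and with centring 16572, 7092 higher and 9480 lower. Relative to the median of all genes, the thermogenesis list was higher by 3.65 (median of members, 19 of 21 by over 1 log2 unit), oxidative phosphorylation by 2.72 (29 of 29) and fatty acid oxidation by 2.91 (19 of 20). White-selective genes stood at -2.21 (10 of 17).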

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

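Of the tests weighed here, the profile of muscle genes across arrays was set before its result was seen, and the other tests were chosen only after the results they bear on, the splits of the samples and the exact test of the endothelial and fibroblast lists included.

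The first pattern is the higher level of matrix, fibroblast and macrophage genes in FXR BAT. Skeletal muscle carried along on FXR BAT 1, 2 and 4 is argued against as the cause, since 59 of the 66 entries of these 3 lists that rose with all arrays (Mfap5 stands in 2 lists) also rose without those arrays. The matrix list stood at 8.77 on FXR BAT 3 and 8.87 on FXR BAT 5 against 8.16 on the highest control array. A lower share of adipocytes that raised every other cell type alike is argued against as well. The endothelial list moved by -0.18 and the fibroblast list by 0.67, a difference of -0.85 (exact two-sided permutation p = 0.00794, the smallest possible, n = 5 and 5). Without the 3 muscle-rich arrays these lists moved by -0.052 and 0.65, a difference of -0.70 (exact permutation p = 0.0476, the smallest possible, n = 5 and 2). Both lists had been called by camera in opposite directions before this test was chosen, so its p-values add little to these shifts. The test does not address a lower share of adipocytes with unequal changes of other cell types, and 13 of 20 mature adipocyte genes fell. A larger share of fibroblasts and macrophages and a higher expression within these cells stay open and were not tested apart, and so does a biological effect of FXR, as a hypothesis.

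The second pattern is the skeletal muscle signal in FXR BAT. Acta1 was 12.72, 12.19 and 12.80 on FXR BAT 1, 2 and 4, 8.00 on FXR BAT 3, 10.58 on FXR BAT 5 and 11.02 on control BAT 3. Ckm was 11.83, 11.16, 11.70, 7.15, 9.42 and 10.28 on the same arrays, both genes named here after their values were seen. Myh1 and Myh2 were 8.63 and 8.33 on FXR BAT 5, above the highest control values of 7.76 and 7.34 on control BAT 3. The fits without FXR BAT 1, 2 and 4 still include FXR BAT 5. A genotype effect on muscle genes in every FXR array cannot be told apart, since FXR BAT 1, 2 and 4 define the pattern and only FXR BAT 3 and 5 are left, with list means of 6.90 and 8.15 against 6.81 to 8.37 in controls. Muscle tissue carried along at dissection stays open: across the 29 muscle genes, the excess of control BAT 3 over the mean of control BAT 4 and 5 correlated with that of FXR BAT 1, 2 and 4 with r of 0.620, 0.776 and 0.412, where over 0.7 on all 3 had been predicted for this cause and 0.3 or less on any against it. A genotype effect in some mice could also give such values and was not tested.

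The third pattern is the number of called genes, 3142 in BAT against 265 in WAT. Fewer arrays in WAT are argued against as the whole cause, since the 25 BAT fits with 4 arrays per group called 1648 to 3787 genes with limma. Intensities near the floor are argued against as the whole cause, because BAT still called 889 and WAT 282 of the 1904 genes at least 4 times the floor in both tissues, adjusted over these genes alone, a ratio of 3.15 against 11.9 over all genes, so that part of the gap may come from the floor. Whether a larger spread between WAT arrays contributes cannot be told apart: its ratio to BAT among these genes was 0.982, with 0.884 to 1.04 when single arrays were left out. A smaller effect of genotype in WAT stays open as a hypothesis, and the median absolute change of these genes was 0.18 in BAT and 0.11 in WAT.

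Other splits of the samples were compared with the real one. For genes changed in BAT, 1 of 100 splits, the real one, gave as many as 3142, and the highest other gave 1. That argues against chance but does not exclude it, since only 100 of 126 possible splits were drawn. For WAT genes the real split was 1 of 35 with as many as 265 (highest other 1). This argues against chance but does not exclude it, since 35 splits are all there are. For the difference between tissues the real assignment was 1 of 100 with 1288 (highest other 78). These draws assume no genotype change in either tissue, so they cannot decide whether the changes differed. For the control tissues the real split was 1 of 100 with 19292, a count that includes the overall offset between tissues. The highest other count for the control tissues was 17225, from splits that partly separate the tissues. Chance cannot be excluded for the number of lists called by camera: 9 of 100 splits gave as many as the 19 in BAT (highest other 20), and 4 of 35 as many as the 15 in WAT (highest other 19).

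Single arrays stood far from the others of their group in 11 of 124 list means and 2 of 72 gene values, where chance gives about 1 in 20, or 6.2 and 3.6. In BAT these were the lymphocyte list on control BAT 5 (6.38, others 6.32 to 6.33), oxidative phosphorylation on FXR BAT 5 (11.40, others 11.56 to 11.63), inflammatory mediators on FXR BAT 3 (6.90, others 7.01 to 7.04) and insulin signalling on FXR BAT 1 (9.32, others 9.25 to 9.27). In control WAT they were thermogenesis on array 2 (6.26, others 6.23), fatty acid oxidation on array 1 (8.37, others 8.47 to 8.49) and insulin signalling on array 2 (8.02, others 7.98). In FXR WAT they were triglyceride synthesis on array 2 (9.76, others 9.61 to 9.62), epithelium on array 1 (6.20, others 5.88 to 5.94), epididymis on array 1 (6.14, others 5.73 to 5.79) and hypoxia on array 3 (7.50, others 7.37 to 7.38). Among genes, Slc4a4 was 8.39 on FXR BAT 1 (others 9.41 to 9.69) and Slc5a7 was 6.41 on FXR WAT 4 (others 7.19 to 7.35).

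The genotype change differed between the tissues for 1288 genes in the interaction test of limma. The differences, WAT change minus BAT change, were 2.61 for Gys2, 2.60 for Elovl3 and 2.12 for Dio2 (Elovl3, Dio2 and Thbs4 near the floor in WAT), 1.99 for Paqr9 and 1.44 for Orm1, and -2.36 for Thbs2, -1.72 for Ogn, -1.66 for Thbs4, -1.60 for Fam13a and -1.50 for Aspn. Outside the named genes, 29 of 1321 probe sets with several symbols and 83 of 11799 with no listed symbol changed in BAT with limma. In WAT 3 probe sets with no listed symbol changed and 0 with several symbols (88 at an unadjusted p below 0.05).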

How the results depend on the processing

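The fits without FXR BAT 1, 2 and 4, with the muscle covariate or with the floor subtracted, and the exact list permutation, centred or not, were chosen only after results were seen. With limma, the count of changed genes in BAT went from 3142 to 4858 with centring on array medians, 1416 without control BAT 2 and 4 (fewer arrays), 1913 without FXR BAT 1, 2 and 4 (fewer arrays, 1570 genes shared) and 318 with a size of at least 1.5-fold. It was 2326 with the muscle covariate, 2953 with the floor subtracted and 2198 to 3685 with 1 array left out. The WAT count of 265 became 414 with array weights, 411 in a fit of all 18 arrays, 59 with at least 1.5-fold and 272 with the floor subtracted. Leaving out 1 array gave 49 (control WAT 1) to 336 (control WAT 3), with 54, 64, 105, 129 and 109 without control WAT 2, control WAT 4, FXR WAT 1, FXR WAT 2 and FXR WAT 4. The difference between tissues gave 727 genes without control BAT 2 and 4 and 908 to 1690 with 1 array left out. Control tissues differed in 11577 genes with quantile normalization, 9571 among genes above the median level (fewer genes tested) and 19176 to 19244 with 1 array left out. Hoxc9 turned from 0.18 to -0.51 with quantile normalization and -0.49 with centring, which remove the overall offset between tissues. Lists called by camera fell from 19 to 1 in BAT and from 15 to 1 in WAT with an estimated correlation. In WAT fry called 3 lists, and the exact permutation 0, with 6 at an unadjusted p below the threshold. With 70 arrangements in WAT, that permutation, centred or not, could pass a list only if many lists shared the smallest p. With each array centred the exact permutation gave 22 lists in BAT (5 higher, 17 lower, 12 of the 13 uncentred ones among them) and 0 in WAT (4 at an unadjusted p below the threshold). Leaving out 1 array gave 19 to 21 lists in BAT and 11 to 15 in WAT, where de novo lipogenesis, mesothelium, inflammatory mediators, endothelium, fatty acid oxidation and the cell cycle each lost their call in at least 1 such fit. The BAT skeletal muscle list turned direction in camera with the muscle covariate (adjusted p = 0.946, limma, unadjusted median 1.72) and without FXR BAT 1, 2 and 4 (median -0.018, adjusted p = 0.977), as follows from removing its own mean or its highest arrays. The correlation of both changes passed with quantile normalization (r = 0.236) and in 9 of the 18 fits with 1 array left out (r from 0.215 to 0.274). Except where the construction shows it, the cause was not tested. No called change named for BAT, WAT or their difference reversed, and reversals were not looked for among named genes that had not passed. For BAT 1805 values stayed on their side of the threshold, 181 lost their call and 2 gained one, and for WAT 736, 188 and 41. For the difference 269 stayed and 1, Orm1 without control BAT 2 and 4, lost it. Of 87 called genes named for BAT, 74 kept their call with each array left out and 53 in every setting, and of 43 for WAT, 12 and 11. The replicate numbers were not taken to pair the samples: same-numbered deviations correlated at -0.493 to 0.276 for BAT and 0.00853 to 0.157 for WAT genotypes, -0.0826 to 0.256 for control tissues and 0.0589 to 0.134 for FXR tissues, and arrays correlated best with their own number in 1 of 5, 1 of 4, 3 of 4 and 3 of 4 cases. Tissues of a genotype matched by number more often than genotypes did, so BAT and WAT from the same mice cannot be excluded. The main test of the difference and the permutations over both tissues treated the tissues as independent. The replicate block gave 2741 genes in BAT, 237 in WAT, 1519 for the difference, 19302 for the tissues, and 20 and 16 lists. Signal over background limits what can be seen: with 58.2% to 62.8% of WAT probe sets near the floor, changes of genes low in WAT are compressed and small ones cannot be excluded. Control means lay at 1.19 to 1.39 times the floor for the called genes Ccl3 and Il7r in BAT and Slc5a7, Inhba and Col12a1 in WAT, so the sizes of these changes are uncertain.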

Other observations

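The comparison with control WAT was predicted before its result was seen, whereas its exact form, the subsets of genes and arrays and the test of imprinted genes were chosen only after results were seen.

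In BAT, 5 further lists were not called by camera, although some of their members were. Of 24 FXR targets in BAT, Slc51b, a bile acid transporter subunit, rose by 0.67 ± 0.19 log2 units, Insig2 fell by 0.19, Vldlr fell by 0.25 and 21 did not pass (0 adjusted over the list alone, 11 at an unadjusted p below 0.05). Without the muscle-rich FXR BAT 1, 2 and 4, 1 FXR target rose and 0 fell. In WAT Vldlr rose by 0.49 and 23 did not pass (1 adjusted over the list alone). The FXR target list was not called by camera (limma, adjusted p = 0.0612 in BAT and 0.541 in WAT), and 5 of the 10 BAT fits with 1 array left out called it. Its mean in BAT moved by 0.079 (exact permutation p = 0.0238, adjusted p = 0.0527), as much as the median gene level per array (0.079). With each array centred on its median it moved by 1.10e-04. The median change of single genes was 0.011, so the centred value may understate the shift. Of 21 genes of the unfolded protein response in BAT, 2 rose, 5 fell and 14 did not pass (5 higher and 6 lower adjusted over the list alone), such as Pdia4 (0.37) and Dnajb9 (-0.67). Without FXR BAT 1, 2 and 4, 2 of these 21 genes rose and 1 fell. In WAT Hspa5, the chaperone BiP, rose by 0.46, Xbp1 fell by 0.18 and 19 did not pass (3 higher and 2 lower adjusted over the list alone). Of 18 NRF2 genes in BAT, 2 rose and 5 fell (2 and 5 adjusted over the list alone), with Gstm2 at 0.26, Txnrd1 at -0.17 and the superoxide dismutase gene Sod2 at -0.40. In WAT Sod2 rose by 0.30 as the only called member of 18. Of 16 clock genes, Ciart (-0.52) and Tef (-0.34) fell in BAT (2 adjusted over the list alone) and Nr1d1 (-0.69) in WAT (2 adjusted over the list alone). Of 20 hypoxia genes in BAT, 2 rose and 3 fell (3 and 7 adjusted over the list alone), with P4ha2 at 0.35 and Egln1 at -0.46.

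Among cell markers not called as lists, 3 of 21 lymphocyte genes rose in BAT (3 adjusted over the list alone), Cd37 by 0.26, Il7r by 0.20 and Cd52 by 0.14. Without the muscle-rich FXR BAT 1, 2 and 4, 1 lymphocyte gene rose. Of 13 Schwann cell and nerve genes 2 rose in BAT (2 adjusted over the list alone), Cnp by 0.39 and Mal by 0.30. The platelet gene Pf4 rose by 0.59 among 5 erythroid and platelet genes (1 adjusted over the list alone). Without FXR BAT 1, 2 and 4, 0 Schwann cell and nerve genes rose and 1 erythroid and platelet gene. Of 20 immediate early genes in BAT, Ccn1 rose by 0.79 and Nr4a2 fell by 0.53 (1 and 1 adjusted over the list alone), and without those arrays 3 rose and 0 fell. In WAT Ebf2 fell by 0.32 as 1 of 21 thermogenesis genes (3 higher and 1 lower adjusted over the list alone). Of 22 triglyceride genes 1 rose, Lpl (4 higher and 7 lower adjusted over the list alone). Of 17 white-selective genes 3 rose and 1 fell (5 and 3 adjusted over the list alone), with Inhba at 1.17 and Agt at -0.44. With limma 0 genes of the epithelium, mesothelium and epididymis lists passed in BAT, and 0 of the epithelium, epididymis, lymphocyte, Schwann cell, erythroid, skeletal muscle, hepatocyte, hypoxia and immediate early gene lists in WAT. At an unadjusted p below 0.05 stood 0, 1 and 0 genes of the BAT lists and 1, 0, 2, 0, 0, 2, 0, 6 and 3 of the WAT lists, in the same order. Adjusted p-values of camera (limma) for the lists not called ran from 0.0612 to 0.845 in BAT and from 0.104 to 0.909 in WAT. Median, mean and test differed in sign for the immediate early gene list in BAT (median 0.02, mean -0.03) and for 5 lists in WAT, none of them called: white-selective adipocyte (median -0.01, mean 0.26), lymphocyte, epididymis, Schwann cell and skeletal muscle.

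On FXR WAT 1, Lcn5 was 8.43, Adam7 7.56 and Rnase9 7.25, against means of 5.80, 5.95 and 5.77 on the other 7 WAT arrays, and 4 of 15 epididymis genes lay above their values on all of these 7. Lcn5, Adam7 and Rnase9 were named here after their values were seen.

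A hypothesis was that FXR BAT moves toward the expression of WAT. Across 19937 genes, which are not independent, the BAT change correlated with control WAT minus control BAT at a median r of 0.472 over 10 divisions of the control BAT arrays into separate sets for both differences (0.402 to 0.530, rho 0.463). The highest of 100 relabellings gave 0.460. The relabellings used a single division each, so an exact version over 252 assignments was run on equal terms: the real one ranked 1, with a highest other r of 0.445 (exact two-sided permutation p = 0.00397, the smallest possible). Among the 1904 brighter genes r was 0.611, and with FXR BAT 3 and 5 alone 0.493. This is consistent with lower thermogenesis and mitochondrial genes and higher matrix genes in FXR BAT, and whether cell composition or cell state underlies it was not tested.

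Another hypothesis was that the rise of the imprinted genes Mest and Peg10 in FXR WAT (Peg10, named after its values were seen, 1.12 ± 0.18) extends to other imprinted genes. The mean of 19 other imprinted genes moved by -0.017 in WAT (exact two-sided permutation p = 0.686, adjusted p = 0.686, n = 4 and 4). Of these 19, 6 had a positive change and 0 were called by limma (3 at an unadjusted p below 0.05). This argues against a rise of these 19 genes as a set. Rises of single members, dim ones above all, cannot be excluded in WAT. In BAT the mean moved by 0.16 (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0159, n = 5 and 5), but by 0.082 without passing once each array was centred on its median (exact permutation p = 0.0952), with 4 genes higher and 1 lower, among them Zim1 (0.79), Meg3 (0.56) and Cdkn1c (-0.46), chosen after their values were seen.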
